A study of Mus musculus with 6 samples.

How the data were processed

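RNA was measured by sequencing in 6 samples of mouse fetal liver cells, 3 with an inducible, FLAG-tagged Arid3a construct and 3 with an inducible construct named LUC in the labels. Per the labels' protocols, total RNA was purified with the Zymo Quick-RNA kit and libraries were made by the standard Illumina procedure. The values used here are the read counts per gene that the authors deposited, 1 whole number per gene and library, with no normalization. The submitters' processing notes name fastp, HISAT2 2.0.5 and featureCounts, with the genome build mm10. The settings of these tools, the annotation release and whether counting used the strand of the reads are not given in the sources used here. Without a stated strand, reads of genes that overlap on opposite strands cannot be told apart, and how reads that align to several places were counted is not given either.

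The deposited count table held 53802 entries, 1 of them a construct entry for mouse Arid3a with a 3xFLAG tag. That entry was kept out of library sizes and gene tests and is reported separately. How reads shared by the construct and the endogenous Arid3a gene were assigned is not given in the sources used here. Each of the 6 columns was matched to its sample by the sample's description. Gene symbols, coordinates and exon lengths came from GENCODE release M21 on GRCm38, the assembly also known as mm10, by exact match of the Ensembl identifier. There were 181 identifiers without a match; they stayed in the tests without a name and took between 0.0305% and 0.0467% of the counts of a library. Library totals ran from 15730908 to 18249053 counts.

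Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with its defaults, libraries were scaled with TMM factors, and Arid3a-FLAG was compared with LUC by the quasi-likelihood F test (glmQLFit and glmQLFTest), with the group as the only term. The test was two-sided, and p-values were adjusted over all 13631 tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Adjusted p-values of single genes are from this test unless another is named. Levels of genes are given as CPM by edgeR's cpm, with library sizes scaled by the TMM factors, as mean ± SD over 3 libraries. The construct's CPM used unscaled library totals. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of the F statistic, and intervals are at the 95% level. Counting intervals and floors cover counting error only. The labels do not say that the replicates came from separate animals, transductions or cultures, so p-values measure the spread between these samples, which may be technical.

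Before the data were examined, 31 gene lists, the rule for naming genes, the test and most alternatives were fixed. The rule named Arid3a and Gata1 in any case. It then took the 12 largest and the 12 smallest log2 fold changes among genes that passed the threshold, averaged at least 5 CPM, had every library of one group above every library of the other and had a symbol that was not a predicted-gene, clone or pseudogene name. It also took up to 4 members of each list with the smallest p, 2 in each direction where both directions held genes past the threshold. Some genes that met the rule are not reported here. Genes named outside the rule are marked in the text as chosen after their values were seen. The lists covered megakaryocytes and platelets, erythroid cells, stem and progenitor cells, mast cells and basophils, neutrophils, monocytes and macrophages, lymphoid cells, hepatocytes, and endothelium and stroma. Others covered G1/S, G2/M, cell cycle inhibitors, p53 targets, activators and inhibitors of apoptosis, MYC targets, TGF-beta response, TGF-beta components, interferon response, NF-kB, immediate early genes and the integrated stress and unfolded protein responses. The rest covered cholesterol synthesis, glycolysis and hypoxia, fetal and imprinted growth genes, reported miR-125b targets, the ARID and GATA families with their partners, mitochondrially encoded genes, replication-dependent histones, sex-linked genes and cytoplasmic ribosomal proteins of at least 20 CPM. They were drawn up from general knowledge of the field, and some genes stand in more than 1 list. For each list the members past the threshold over all genes were counted, and again with p-values adjusted over the list alone. The 28 lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Arid3a itself was left out of every list.

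Alternatives were RLE and upper quartile factors, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit with the replicate number as a block, each library left out in turn, the 20 most abundant genes left out, an adjusted p under 0.01, and a fold tested against 1.5. List tests were repeated with an estimated inter-gene correlation and without members that other lists shared or that belonged to the cell cycle. The lists were also tested with fry, which asks whether a set changed at all and not whether it changed more than other genes. Alternatives chosen after the data were seen were a correction for exon length (a smooth trend of each library against log exon length used as an offset), that correction without LUC library 2, and construct counts added to Arid3a. No library was left out of the main comparison. The 6 libraries were also split into 3 and 3 in all 10 ways.

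The steps were tested on simulated data before use. For Arid3a-FLAG against LUC with 3 simulated libraries each and 13451 genes tested, edgeR found 53.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 9 of 181 calls were false. With a length trend added to LUC library 2 and 13477 genes tested, it found 64% of changed genes without the length correction and 76% with it. False calls were not counted for that simulation, and the trend lay in LUC library 2 alone. It therefore does not test the correction where a trend is shared by a group. In both simulations genes were drawn independently of each other, and the first held no length trend. The shares of genes found and of false calls may therefore not hold for the measured data. In the measured data the common biological coefficient of variation was 11.9%. Each pair of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 4.88 to 33.9, so none was treated as a second sequencing of another. Libraries made separately from the same culture could also differ by more than sampling noise. The values therefore do not show that the replicates are independent.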

Results

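Transcripts were counted in mouse fetal liver cells taken at E12.5-13.5 from a strain that carries Cas9 and EGFP. Cells at this stage include blood progenitors. Per the labels, the cells carried a guide against Gata1 and are named for Gata1s, the short form of the blood transcription factor GATA1, and a lentivirus supplied the microRNA miR-125b. A further construct, switched on with doxycycline at 1 μg/mL for 48 h, encoded either FLAG-tagged Arid3a (3 libraries) or LUC (3 libraries). Arid3a is a DNA-binding protein of the ARID family. Total counts were 16805801, 16605860 and 18249053 in the LUC libraries and 16019716, 17014650 and 15730908 in the Arid3a-FLAG libraries.

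The comparison asked which genes changed when Arid3a was induced in these Gata1s, miR-125b cells. The series title links ARID3A to megakaryocytes, the cells that make platelets, and to restraint of leukaemia. The construct was found where the labels place it. It had 3348, 3044 and 2758 counts in the Arid3a-FLAG libraries, a mean of 187.7 ± 18.5 CPM (SD, n = 3), and 0 counts in each LUC library. Against a floor of 3 counts per LUC library it was at least 970-fold higher with Arid3a-FLAG. The endogenous Arid3a gene (ENSMUSG00000019564, chromosome 10, 79927043 to 79955018, plus strand, mm10) stood at 15.9, 9.22 and 14.03 CPM with LUC and 12.6, 13.6 and 12.8 CPM with Arid3a-FLAG. This gave a log2 fold change of -0.01 (95% interval -0.42 to 0.40, adjusted p = 0.977). With the construct's counts added to those of the gene, an alternative chosen after the data were seen, Arid3a rose by 3.92 on the log2 scale (SE 0.17, adjusted p = 3.8e-06). The LUC libraries had 276, 141 and 260 counts on the gene and 0 on the construct. How reads common to both were assigned is not given, so the -0.01 and the 3.92 may each leave out part of the Arid3a reads. Neither is a sure measure of the change in Arid3a transcripts. Gata1 (ENSMUSG00000031162, chromosome X, 7959260 to 7978071, minus strand) had 285.6 ± 29.0 CPM with LUC and 325.8 ± 6.13 CPM with Arid3a-FLAG, a log2 fold change of 0.19 (SE 0.10, 95% interval -0.03 to 0.41, adjusted p = 0.249). Gene counts do not tell edited from unedited Gata1 transcripts.

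**Figure D1:**
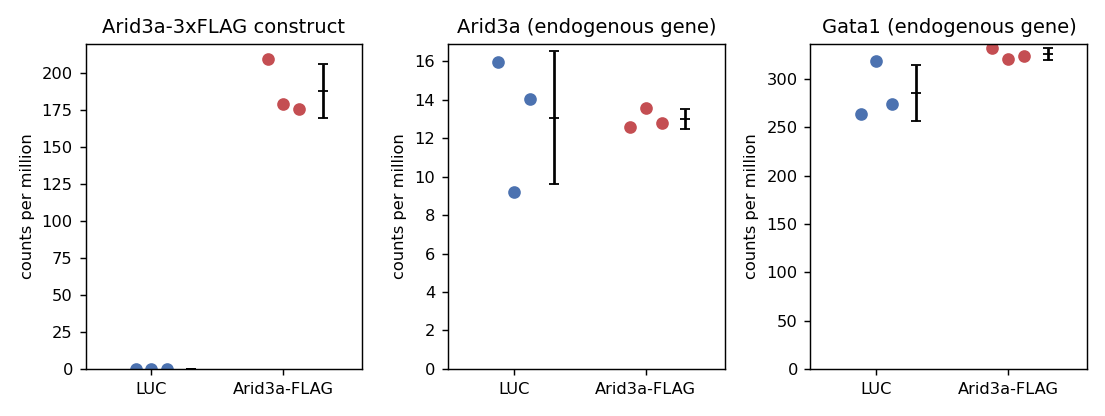
CPM of the Arid3a-3xFLAG construct, the endogenous Arid3a gene and Gata1 in each LUC (blue) and Arid3a-FLAG (red) library, with the mean and SD of each group in black. The construct was at 0 in the 3 LUC libraries and averaged 187.7 CPM in the Arid3a-FLAG libraries, while endogenous Arid3a ran from 9.22 to 15.9 CPM with LUC and from 12.6 to 13.6 CPM with Arid3a-FLAG.

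With Arid3a-FLAG, 467 genes were higher and 527 were lower out of 13631 tested, and 284 of these 994 differed by more than 2-fold. Among called genes that averaged at least 5 CPM with the groups fully separated, the largest rise was that of Thbs1 (chromosome 2, 118111876 to 118127133), which encodes thrombospondin-1, a glycoprotein stored in platelets. It went from 46.9 ± 24.4 to 281.7 ± 23.9 CPM (SD, n = 3), a log2 fold change of 2.58 (SE 0.28, adjusted p = 0.00067). Prrt4 (chromosome 6, 29169232 to 29179584), a proline-rich transmembrane protein, rose 5.33-fold to 106.8 ± 2.61 CPM, or by 2.41 on the log2 scale (SE 0.14, adjusted p = 2.9e-05). Mapt (chromosome 11, 104231390 to 104332090), the microtubule-associated protein tau, rose from 14.6 ± 3.32 to 65.4 ± 4.15 CPM, or by 2.16. Map1a, another microtubule-associated protein, rose by 1.70, Syt13, a synaptotagmin, by 2.10, and Plxna4, a semaphorin receptor, by 1.63. The glypican Gpc4 rose from 15.4 ± 3.64 to 68.7 ± 5.75 CPM (2.15 on the log2 scale). Exoc3l4 rose by 2.16, the adenylyl cyclase Adcy9 by 2.11, the cation exchanger Slc24a1 by 2.10, the adult alpha globin Hba-a1 by 1.93 and the splicing factor Usp39 by 1.77. Map1a overlaps Ppip5k1 and Exoc3l4 overlaps Gm10425 on the opposite strand, and Hba-a1 has a near-identical copy in Hba-a2, so these values are uncertain.

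Under the same limits the largest fall was that of Gzmd (chromosome 14, 56129556 to 56132608), a granzyme of cytotoxic lymphocyte granules. It fell 9.51-fold, from 148.6 to 15.7 CPM (log2 fold change -3.25, SE 0.18, adjusted p = 2.9e-05). Nkg7 (chromosome 7, 43437073 to 43438249), a membrane protein of the same granules, went from 26.5 ± 7.43 to 3.53 ± 0.403 CPM (-2.90), and the basophil protease Mcpt8 (chromosome 14, 56082166 to 56085273) from 57.0 ± 11.4 to 10.6 ± 4.48 CPM (-2.43). The natural killer receptor Klra1 (-1.65), the C-type lectin Clec4e (-2.35), the chemokine Ccl6 (-1.83) and Tnfrsf8, which encodes CD30 (-1.94), also fell. Col12a1, a collagen, went from 112.1 ± 23.8 to 25.8 ± 5.37 CPM (-2.12). The G protein subunit Gnai1 (-2.23), the long non-coding RNA AI838599 (-1.90), the phospholipid transfer protein Pltp (-1.64) and Epb41l4b (-1.64) completed the list. Gzmd lies in a cluster of similar granzyme genes, Klra1 in the Ly49 family, and Pltp overlaps Ctsa on the opposite strand, which leaves their values uncertain.

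All 24 of these genes kept their direction and their call in each of the 6 fits that left out 1 library and under each other alternative for which single genes were compared, with an adjusted p of at most 0.027. Their calls against a fold of 1.5 were not compared. Full separation of the groups in these same 6 libraries was a condition of their choice. A change of direction with 1 library left out was therefore hardly possible, and a kept call was likely. The counts of genes moved with single libraries: 189 were higher and 239 lower without LUC library 1, 1191 and 1095 without LUC library 2, 612 and 437 without LUC library 3, 115 and 118 without Arid3a-FLAG library 1, 131 and 163 without library 2, and 209 and 356 without library 3. LUC library 2 stood apart from the others on the second principal component of log2 CPM (24.0% of the variance), and the first (45.3%) separated the groups. Of the 994 genes, 990 remained past the threshold in the same direction without LUC library 2.

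**Figure D2:**
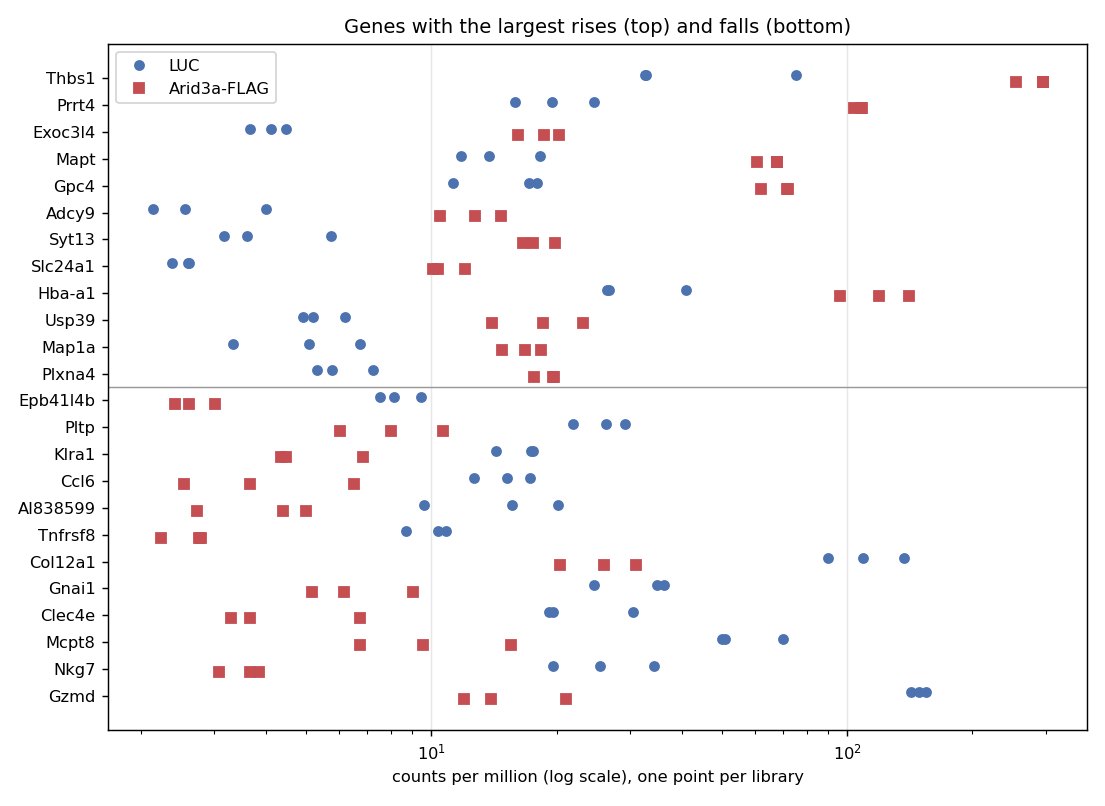
CPM (log axis) in each LUC (blue circles) and Arid3a-FLAG (red squares) library for the 12 largest rises, above the line, and the 12 largest falls, below it, among called genes of at least 5 CPM on average. The groups do not overlap for any of the 24, a condition of their choice; Gzmd averaged 148.6 CPM with LUC and 15.7 CPM with Arid3a-FLAG.

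Genes of the megakaryocyte and platelet list mostly rose where they changed. Of 47 tested members, 10 rose, 3 fell and 34 did not pass (20 rose and 4 fell when adjusted over the list alone). The rises numbered 6 without Arid3a-FLAG library 1 or 2 and 18 without LUC library 2, and the falls 1 without LUC library 1, LUC library 3, Arid3a-FLAG library 1 or Arid3a-FLAG library 3. Besides Thbs1, Itgb3, the beta chain of the platelet fibrinogen receptor, rose from 372.4 ± 49.0 to 727.8 ± 39.5 CPM (0.97 on the log2 scale, SE 0.11, adjusted p = 0.0010). Among genes chosen after their values were seen, 3 subunits of the platelet receptor for von Willebrand factor rose, Gp1bb by 0.82, Gp9 by 0.69 and Gp5 by 0.63. Gp1bb overlaps Sept5 on the same strand, so its value is uncertain. The call of Gp9 was lost without Arid3a-FLAG library 1 (adjusted p = 0.080). In contrast, the platelet chemokine Ppbp fell from 654.8 ± 119 to 324.6 ± 35.8 CPM (-1.01, SE 0.14, adjusted p = 0.0030). The collagen receptor chain Itga2 fell by 0.72 (adjusted p = 0.039, up to 0.163 with 1 library left out). Pf4, a second platelet chemokine, and Itga2b, the alpha chain of the fibrinogen receptor, also chosen after their values were seen, did not pass, with log2 fold changes of -0.33 (SE 0.16) and 0.22 (SE 0.11). As a set the list was higher (median 0.25, camera adjusted p = 2.3e-05; adjusted p = 0.802 with an estimated correlation).

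Erythroid genes moved in both directions, with more rises. Of 32 tested members, 9 rose, 3 fell and 20 did not pass (14 rose and 4 fell when adjusted over the list alone). The rises numbered 5 without LUC library 1, Arid3a-FLAG library 1 or Arid3a-FLAG library 3 and 14 without LUC library 2, and the falls 1 without LUC library 1 or Arid3a-FLAG library 1 or 2 and 5 without LUC library 2. Kel, a blood group protease of the red cell membrane, rose from 11.6 ± 2.12 to 34.8 ± 1.30 CPM (1.58, SE 0.14, adjusted p = 0.00024), alongside Hba-a1. Of genes chosen after their values were seen, the membrane skeleton protein Epb42 rose from 1.73 ± 0.252 to 7.20 ± 0.353 CPM (2.05), the embryonic alpha-like globin Hba-x from 0.0963 ± 0.0270 to 1.71 ± 0.331 CPM (4.03), and Hba-a2 by 2.91. Hba-a2 is near-identical to Hba-a1, so its value is uncertain too. The beta globin Hbb-bs, also chosen so, had a log2 fold change of 0.72 (SE 0.22, adjusted p = 0.077). The water channel Aqp1 fell by 1.12 (adjusted p = 0.019, up to 0.097 with 1 library left out). The carbonic anhydrase Car1, chosen after its values were seen, also fell past the threshold. Its log2 fold change ran from -1.34 to -0.91 with 1 library left out. The call of Car1 was lost in 4 of 6 such fits (adjusted p up to 0.146). The set was higher (median 0.23, camera adjusted p = 0.00037; adjusted p = 0.802 with an estimated correlation).

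In the stem and progenitor list 1 of 24 tested members rose, 5 fell and 18 did not pass (3 rose and 7 fell when adjusted over the list alone). The falls numbered 2 without Arid3a-FLAG library 1 or 2, and without LUC library 2 there were 4 rises and 10 falls. Ly6a, which encodes the stem cell antigen Sca-1, fell from 121.6 to 43.6 CPM (-1.48, SE 0.21, adjusted p = 0.0033). The ETS factor Erg fell from 70.4 ± 6.99 to 32.6 ± 5.19 CPM (-1.11, SE 0.13, adjusted p = 0.00088). Tal1, a master regulator of blood formation, rose by 0.38 (adjusted p = 0.044, up to 0.179 with 1 library left out). The set did not pass (median -0.14, camera adjusted p = 0.321).

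**Figure D3:**
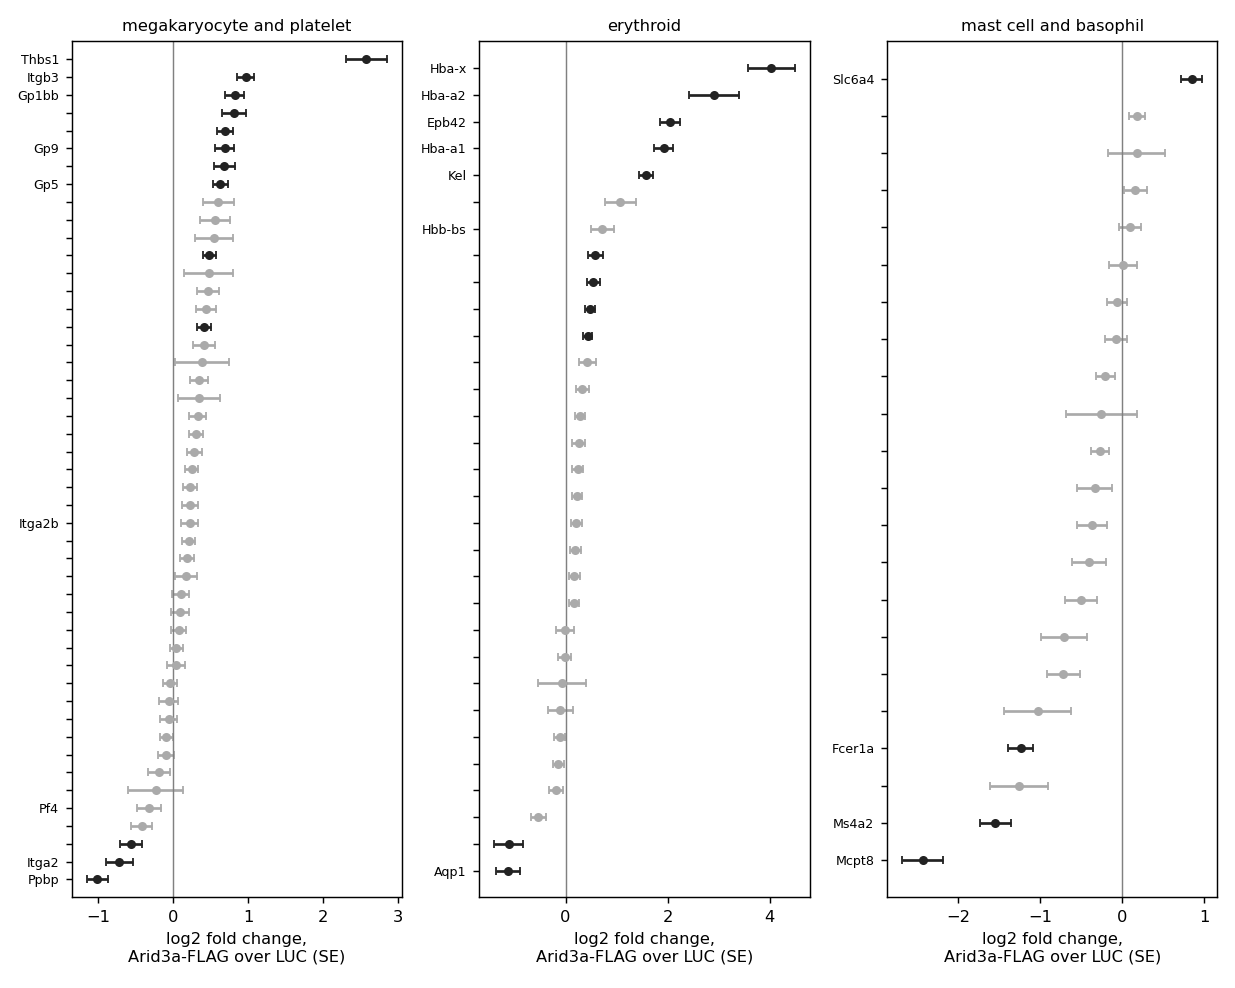
Log2 fold change of Arid3a-FLAG over LUC, with its SE, for tested members of the megakaryocyte and platelet, erythroid, and mast cell and basophil lists. The genes named in the text are labelled, except Car1 and Cpa3, and 1 erythroid member is not shown. Black marks genes past the adjusted p threshold and grey the rest. In the full lists 10, 9 and 1 members rose and 3, 3 and 3 fell.

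Tested markers of other blood lineages were lower where they changed, with Csf1r and Slc6a4 as exceptions. Many listed markers did not pass the filter on low counts. It left 6 of 28 neutrophil, 12 of 28 monocyte and macrophage, 4 of 28 lymphoid, and 22 of 26 mast cell and basophil genes. Of 22 tested mast cell and basophil genes, 1 rose, 3 fell and 18 did not pass (1 rose and 5 fell when adjusted over the list alone). The falls numbered 6 without LUC library 2 and 7 without Arid3a-FLAG library 3. Ms4a2, the beta chain of the high-affinity IgE receptor, fell from 273.2 ± 17.3 to 93.8 ± 32.5 CPM (-1.54, SE 0.19, adjusted p = 0.0014). Its alpha chain Fcer1a, chosen after its values were seen, fell from 748.2 ± 97.4 to 317.4 ± 67.6 CPM (-1.24), and Mcpt8 is given above. Cpa3, another mast cell gene chosen so, did not pass. The serotonin transporter Slc6a4, which platelets also use, rose from 54.7 ± 11.1 to 98.5 ± 2.01 CPM (0.85, SE 0.13, adjusted p = 0.0051). The set was lower (median -0.30, camera adjusted p = 0.030; adjusted p = 0.839 with an estimated correlation). Its call was lost without LUC library 2 (adjusted p = 0.059), LUC library 3 (0.130), Arid3a-FLAG library 1 (0.089) or Arid3a-FLAG library 2 (0.082).

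Of 6 tested neutrophil and granulocyte genes, 3 fell and 3 did not pass (3 fell when adjusted over the list alone; set median -0.55, camera adjusted p = 0.104). With no filter on low counts 22 members were tested and the median was 0.51. The 3 genes that fell were Ms4a3, at 5.37 ± 0.814 CPM with LUC and 1.83 ± 0.137 CPM with Arid3a-FLAG (-1.55), and the granule proteases Ctsg (-1.31) and Prtn3 (-1.01). The calls of Ctsg and Prtn3 were lost in 3 of 6 fits that left out 1 library (adjusted p up to 0.091 and 0.153). Of 4 tested lymphoid genes, 3 fell and 1 did not pass, the same counts as when adjusted over the list alone. In both the neutrophil and the lymphoid list 1 fell without LUC library 1 or Arid3a-FLAG library 1 or 2. Beside Nkg7, the interleukin 7 receptor Il7r fell by 1.21, from 7.43 ± 1.33 CPM, and the T cell factor Lef1 fell by 2.25, from 0.797 ± 0.168 CPM. The calls of Il7r and Lef1 were lost in some fits with 1 library left out (adjusted p up to 0.076 and 0.093). Of 12 tested monocyte and macrophage genes, 1 rose, 1 fell and 10 did not pass (2 rose and 3 fell when adjusted over the list alone; set median -0.10, mean 0.05, camera adjusted p = 0.909). Csf1r, the receptor for macrophage colony-stimulating factor, rose from 2.62 ± 0.689 to 7.89 ± 0.651 CPM (1.59, SE 0.22, adjusted p = 0.0030). Without Arid3a-FLAG library 3, 3 of this list fell. Irf8, a transcription factor of monocytes, fell by 0.72 (adjusted p = 0.032, up to 0.137 with 1 library left out). Csf1r overlaps Hmgxb3 on the opposite strand, so its value is uncertain.

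Of 3 tested hepatocyte genes none passed in edgeR (2 were lower when adjusted over the list alone and at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0). Afp, the fetal serum protein of hepatocytes, stood at 22.1 ± 3.56 CPM with LUC and 18.1 ± 2.10 CPM with Arid3a-FLAG. Of 10 tested endothelial and stromal genes, 2 rose, 2 fell and 6 did not pass (2 rose and 3 fell when adjusted over the list alone; set median -0.19, mean 0.01, camera adjusted p = 0.713). None fell past the threshold without Arid3a-FLAG library 1 or 2. Kdr, a receptor for vascular endothelial growth factor, rose by 2.32 from 0.345 ± 0.136 CPM, and Sparc, a secreted matrix protein, rose by 0.80 (adjusted p = 0.0095, 0.064 without Arid3a-FLAG library 1). The intermediate filament Vim fell from 418.4 ± 52.5 to 234.0 ± 53.4 CPM (-0.84, adjusted p = 0.012, up to 0.079 with 1 library left out). Pdgfrb, a receptor for platelet-derived growth factor, fell by 1.37 (adjusted p = 0.022, up to 0.111).

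None of 49 tested G1/S genes passed in edgeR, over all genes or when adjusted over the list alone (2 were higher and 3 lower at an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0). Without LUC library 2, 4 were higher and 1 lower. The set did not pass (median -0.03, mean -0.02, camera direction higher, adjusted p = 0.886). Of 58 tested G2/M genes, 3 fell and 55 did not pass (3 fell when adjusted over the list alone). At an unadjusted p under 0.05, 2 were higher and 15 lower, 40 of the 58 lay below 0, and DESeq2 called 5 lower. No G2/M gene passed without any 1 of the Arid3a-FLAG libraries, and without LUC library 2 there were 2 rises and 6 falls. The 3 that fell in the main comparison were the centromere histone Cenpa (-0.46, adjusted p = 0.018), Psrc1 (-0.48, 0.022) and the spindle protein Nusap1 (-0.39, 0.034). Each was lost in at least 3 of 6 fits with 1 library left out (adjusted p up to 0.127, 0.126 and 0.163). The G2/M set had a median of -0.09 and did not pass (camera adjusted p = 0.102), although it did with the exon length correction (0.0082). Of 23 tested cell cycle inhibitors, 3 rose and 20 did not pass (3 rose when adjusted over the list alone). The rises numbered 1 without Arid3a-FLAG library 2 or 3, and none passed without library 1. Btg2, an antiproliferative factor, rose from 73.6 ± 5.05 to 109.9 ± 13.6 CPM (0.58, adjusted p = 0.012, 0.072 without Arid3a-FLAG library 1). Gadd45g rose by 0.45 and the retinoblastoma gene Rb1 by 0.32, with adjusted p of 0.018 and 0.047 that reached 0.107 and 0.189 with 1 library left out. The inhibitor set was higher (median 0.12, camera adjusted p = 0.032; adjusted p = 0.802 with an estimated correlation). This call was lost without LUC library 1 (adjusted p = 0.060), LUC library 2 (0.083), Arid3a-FLAG library 1 (0.117) or Arid3a-FLAG library 3 (0.063).

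Genes of p53 and apoptosis gave few calls. Of 32 tested p53 targets, Btg2 rose, the DNA repair gene Ddb2 fell (-0.67, adjusted p = 0.042, up to 0.170 with 1 library left out) and 30 did not pass, also when adjusted over the list alone (set median 0.01, camera adjusted p = 0.553). None of 31 activators of apoptosis passed in edgeR (0 also when adjusted over the list alone; 1 higher and 4 lower at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom; set median -0.02, camera direction higher, adjusted p = 0.992). None of 16 inhibitors of apoptosis passed either (0 also when adjusted over the list alone; 2 higher and 1 lower at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom; set median 0.07, camera adjusted p = 0.321). Of 42 MYC targets and ribosome biogenesis genes, Rrp12 rose by 0.38 (adjusted p = 0.022, up to 0.130 with 1 library left out) and 41 did not pass, also when adjusted over the list alone. That set had a median of -0.03 and a mean of 0.01 and did not pass (camera direction higher, adjusted p = 0.368). Without LUC library 2 the set was higher (adjusted p = 0.0014) and 9 members rose. In the same fit 2 activators of apoptosis rose and 1 fell, and 2 inhibitors rose.

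Of 31 tested TGF-beta response genes, 6 rose, 1 fell and 24 did not pass (10 rose and 3 fell when adjusted over the list alone; set median 0.12, camera adjusted p = 0.094, and 0.014 without LUC library 3). The rises numbered 2 without LUC library 1 or Arid3a-FLAG library 2 and 3 without Arid3a-FLAG library 1 or 3, and the falls 3 without LUC library 2. Thbs1 and Ltbp2, an extracellular matrix protein, rose, the second from 2.13 ± 0.611 to 5.78 ± 0.879 CPM (1.43, adjusted p = 0.0093, 0.052 without Arid3a-FLAG library 2). Pmepa1, an inhibitor of TGF-beta signalling, fell by 1.01 (adjusted p = 0.019, up to 0.100 with 1 library left out). Of 19 tested ligands, receptors and SMADs, 2 rose, 2 fell and 15 did not pass (2 rose and 3 fell when adjusted over the list alone; set median 0.00, mean -0.08, camera adjusted p = 0.909). Without LUC library 1 or Arid3a-FLAG library 1 or 2 there was 1 rise and 1 fall, and without LUC library 2 there were 3 and 5. Ltbp1, which anchors latent TGF-beta in the matrix, rose from 33.5 ± 2.56 to 93.6 ± 12.3 CPM (1.48, SE 0.12, adjusted p = 0.00012). Its relative Ltbp4 fell from 16.2 ± 2.48 to 7.55 ± 1.53 CPM (-1.10, SE 0.18, adjusted p = 0.0065). The signal transducer Smad3 rose by 0.52 and the ligand Tgfb3 fell by 1.47, with adjusted p of 0.018 and 0.032 that reached 0.110 and 0.125 with 1 library left out. Tgfb3 overlaps Ttll5 on the opposite strand, as do Ddb2 and Acp2, Nusap1 and Oip5, Prtn3 and Plppr3, and Rb1 with Rcbtb2 and Lpar6, so these values are uncertain.

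Of 25 tested NF-kB and inflammatory genes, 1 rose, 7 fell and 17 did not pass (4 rose and 11 fell when adjusted over the list alone). The falls numbered 1 without Arid3a-FLAG library 1 or 2, 4 without LUC library 1 and 10 without LUC library 2, and the rises 3 without LUC library 2 or 3. Traf1, an adaptor of TNF receptors, fell from 11.2 ± 0.599 to 4.39 ± 0.280 CPM (-1.35, SE 0.16, adjusted p = 0.00088). The NF-kB subunit Relb fell by 0.57 (adjusted p = 0.014, up to 0.084 with 1 library left out). The adhesion receptor Cd44 rose by 0.40 (adjusted p = 0.026, up to 0.141). The set was lower (median -0.36, camera adjusted p = 0.032; adjusted p = 0.802 with an estimated correlation). This call was lost with the exon length correction (adjusted p = 0.073) and without LUC library 1 (0.060), LUC library 3 (0.175) or Arid3a-FLAG library 1 (0.207). Of 28 tested interferon response genes, Bst2 (-0.50) and Isg20 (-0.53) fell and 26 did not pass, also when adjusted over the list alone. Their adjusted p of 0.031 and 0.045 reached 0.129 and 0.178 with 1 library left out, and neither passed without LUC library 1 or any 1 of the Arid3a-FLAG libraries. The set did not pass (median -0.06, camera adjusted p = 0.414).

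Of 25 tested immediate early genes, 5 rose and 20 did not pass (8 rose when adjusted over the list alone). The rises numbered 2 without Arid3a-FLAG library 1 and 3 without Arid3a-FLAG library 3 or LUC library 1. The phosphatase Dusp4 rose from 29.6 ± 5.34 to 64.6 ± 6.29 CPM (1.13, SE 0.14, adjusted p = 0.0012). The AP-1 genes Fosb and Fos rose from low levels. Fosb went from 0.383 ± 0.143 to 8.73 ± 7.66 CPM (4.45, SE 0.70, adjusted p = 0.0052). Fos went from 0.934 ± 0.485 to 5.55 ± 3.31 CPM (2.53, SE 0.55, adjusted p = 0.022, up to 0.097 with 1 library left out). Zfp36, which promotes decay of cytokine transcripts, rose by 1.19 (adjusted p = 0.014, 0.060 without Arid3a-FLAG library 1). The set was higher (median 0.25, camera adjusted p = 0.023; adjusted p = 0.802 with an estimated correlation). Its call was lost without LUC library 1 (adjusted p = 0.081), LUC library 2 (0.083) or Arid3a-FLAG library 3 (0.074). Of 30 tested genes of the integrated stress and unfolded protein responses, the lipoprotein receptor Vldlr rose from 94.7 ± 12.1 to 153.6 ± 11.7 CPM (0.70, adjusted p = 0.0051) and 29 did not pass, also when adjusted over the list alone (set median 0.07, camera adjusted p = 0.143, and 0.013 without LUC library 3). Without LUC library 2 or 3, 5 of these genes rose.

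Of 25 tested cholesterol synthesis genes, 3 rose, 1 fell and 21 did not pass (5 rose and 1 fell when adjusted over the list alone). The rises numbered 12 without LUC library 2 and 1 without Arid3a-FLAG library 3, and no member rose past the threshold without LUC library 1 or Arid3a-FLAG library 1 or 2. The enzyme Hsd17b7 rose by 0.52 (adjusted p = 0.018, up to 0.100 with 1 library left out). The set was higher (median 0.15, camera adjusted p = 0.023; adjusted p = 0.802 with an estimated correlation). The call was lost without LUC library 1 (adjusted p = 0.060), LUC library 3 (0.052), Arid3a-FLAG library 1 (0.089) or Arid3a-FLAG library 2 (0.061). Of 31 tested glycolysis and hypoxia genes, 1 rose, 2 fell and 28 did not pass (2 rose and 2 fell when adjusted over the list alone; set median -0.04, camera adjusted p = 0.553). None passed without Arid3a-FLAG library 1 or 2, and without LUC library 2 there were 2 rises and 5 falls. The glucose transporter Slc2a3 rose by 0.55, the collagen hydroxylase P4ha2 fell by 1.59 and the carbonic anhydrase Car9 fell by 0.63, with adjusted p of 0.039, 0.013 and 0.021 that reached 0.173, 0.062 and 0.116 with 1 library left out. Car9 overlaps Gm12454 on the opposite strand and Slc2a3 overlaps Gm4482 on the same strand, so their values are uncertain.

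Of 11 tested fetal and imprinted growth genes, 2 rose, 1 fell and 8 did not pass, also when adjusted over the list alone (set median 0.20, camera adjusted p = 0.309). Igf2r, the receptor that clears IGF2, rose from 4.32 ± 1.13 to 12.1 ± 1.99 CPM (1.48, adjusted p = 0.0040). The insulin signalling adaptor Irs2 rose from 50.6 ± 11.6 to 95.9 ± 2.83 CPM (0.92, adjusted p = 0.0053). The RNA-binding protein Igf2bp2 fell by 0.95 (adjusted p = 0.020, up to 0.110 with 1 library left out). Of 27 tested reported targets of miR-125b, which both groups carried, the phosphatase Ptpn18 fell by 0.81 (adjusted p = 0.021, up to 0.101 with 1 library left out) and 26 did not pass, also when adjusted over the list alone (set median -0.03, mean -0.00, camera direction higher, adjusted p = 0.734). Without LUC library 2, 3 targets rose and 2 fell. Of 27 tested ARID, GATA and partner genes, 2 rose, 1 fell and 24 did not pass, also when adjusted over the list alone (set median 0.07, camera adjusted p = 0.143, and 0.037 without LUC library 3). The rises numbered 6 without LUC library 2 and 1 without LUC library 1 or any 1 of the Arid3a-FLAG libraries. Mef2c, a transcription factor active in megakaryocytes, rose from 163.2 ± 17.9 to 253.3 ± 13.2 CPM (0.63, adjusted p = 0.0058) beside Tal1. Arid5b fell by 1.42 from 1.74 ± 0.375 CPM (adjusted p = 0.030, up to 0.145 with 1 library left out). Ptpn18 overlaps Gm28417 and Igf2r overlaps Airn on the opposite strand, so their values are uncertain.

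Cytoplasmic ribosomal protein genes were lower as a set: all 83 tested members had a log2 fold change below 0, with a median of -0.38 (camera adjusted p = 1.4e-10; adjusted p = 0.839 with an estimated correlation). Only Rpl29 passed by itself (-0.57, adjusted p = 0.028, up to 0.148 with 1 library left out), and 0 passed when adjusted over the list alone, with 59 lower at an unadjusted p under 0.05 and 18 lower by DESeq2. There were 58 called lower with no filter on low counts, 12 without LUC library 2 and 9 without LUC library 3. The median moved with LUC library 2, in which short transcripts were more abundant. Without it the median was -0.16, with the exon length correction -0.20 and with both -0.10. Over all tested genes the log2 fold change rose with exon length (Spearman rho across genes, which are not independent replicates, 0.324), and rho was 0.165 without LUC library 2. Of 13 mitochondrially encoded genes, mt-Co2 (-0.79) and mt-Atp6 (-0.67) fell and 11 did not pass (3 lower when adjusted over the list alone; set median -0.26, camera adjusted p = 0.321). Both calls were lost without Arid3a-FLAG library 1 or 2 and with the exon length correction, and both genes have nuclear copies, which leaves their values uncertain. None of 20 tested replication-dependent histones passed in edgeR (0 also when adjusted over the list alone; 1 higher at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom; set median 0.08, camera adjusted p = 0.337, and 0.015 with the exon length correction). Of the sex-linked genes only Xist was tested, at 1037.6 ± 406 CPM with LUC and 993.5 ± 24.4 CPM with Arid3a-FLAG (-0.06, SE 0.24, adjusted p = 0.894; 0 also by DESeq2, limma-voom and at an unadjusted p under 0.05). Without LUC library 2 its value was -0.33 and passed (adjusted p = 0.010).

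**Figure D4:**
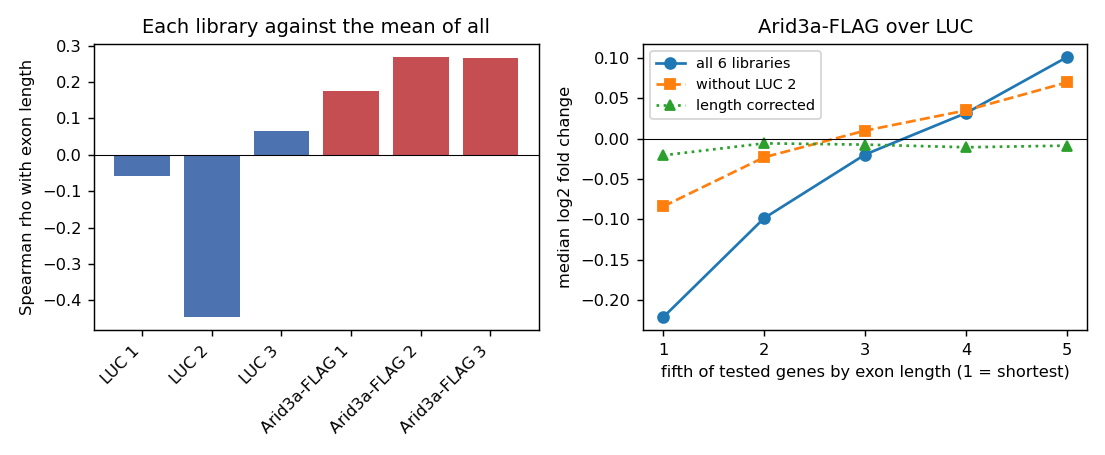
Left, the Spearman rho between each gene's deviation from its mean over all libraries and its exon length, for each LUC (blue) and Arid3a-FLAG (red) library; right, the median log2 fold change of Arid3a-FLAG over LUC in 5 groups of genes of increasing exon length, with all 6 libraries, without LUC library 2 and with the length correction. LUC library 2 had a rho of -0.447, and the median ran from -0.22 in the shortest to 0.10 in the longest group with all 6 libraries.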

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

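The choices of test, filter and lists were made before the data were examined, except those named as later in the processing text. Counts of genes moved most with the threshold and with single libraries. With no filter on low counts 869 genes were higher and 1076 lower, DESeq2 called 771 higher and 790 lower, an adjusted p under 0.01 left 125 and 137, and a fold tested against 1.5 left 48 and 57. Leaving out 1 library gave 115 to 1191 higher and 118 to 1095 lower, and the exon length correction without LUC library 2 gave 990 and 1048. With the replicate number as a block, 813 of the 994 genes kept their call. Deviations from the group mean correlated at -0.10, -0.11 and 0.12 between libraries of the same number. These values lie within the -0.18 to 0.21 between libraries of different numbers. With 3 libraries per group they can neither show nor exclude a pairing. The log2 fold change of Arid3a was near 0 and changed sign: 0.0035 with no filter on low counts, 0.016 with limma-voom, 0.0185 with the replicate block, 0.0039 without the 20 most abundant genes, -0.19 to 0.17 with 1 library left out, and 3.92 with construct counts added. Xist was at 0.0334 with limma-voom, 0.0231 with the replicate block and -0.33 to 0.20 with 1 library left out, and Nr4a1 at -0.0219 with limma-voom and -0.21 to 0.33 with 1 library left out. Of 1474 repeats for the 93 named genes past the threshold, 159 lost the call; of 742 for the 47 others, 95 gained one and 8 changed sign.

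The list tests were less stable. Of the 8 lists called, 0 kept the call with an estimated inter-gene correlation, 0 by fry, 7 by fry mixed, which counts changes in either direction, and 4 to 6 with 1 library left out. Over all 28 lists, 0, 0, 20 and 4 to 8 were called. With an estimated inter-gene correlation the adjusted p was 0.802 for the megakaryocyte and platelet, erythroid, cell cycle inhibitor, NF-kB, immediate early and cholesterol synthesis lists, and 0.839 for the mast cell and ribosomal protein lists. By fry, which tests against no change and not against other genes, it was 0.0955 for the megakaryocyte and platelet and the NF-kB lists, 0.0514 for the erythroid list, 0.304 for mast cells, 0.184 for cell cycle inhibitors, 0.249 for immediate early genes, 0.229 for cholesterol synthesis and 0.310 for ribosomal proteins (0.143 by fry mixed). Over all alternatives the adjusted p of the megakaryocyte and platelet list ran from 4.2e-07 to 0.802 and that of the erythroid list from 7.7e-07 to 0.802. With 1 library left out it ran from 3.9e-05 to 0.130 for mast cells, 0.0068 to 0.117 for cell cycle inhibitors, 0.0045 to 0.207 for NF-kB, 0.0017 to 0.0827 for immediate early genes and 0.0014 to 0.0886 for cholesterol synthesis. The NF-kB call was also lost with no filter on low counts (0.069) and with the exon length correction (0.073). The cell cycle inhibitor call was lost with at least 5 CPM (0.0612) and without shared genes (0.0641), and the immediate early call with at least 5 CPM (0.0612).

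Lists that did not pass in the main comparison changed direction in 28 of 398 repeats and gained a call in 30, of which 13 were by fry mixed. None of those that changed direction passed. For apoptosis activators it was 0.975 with upper quartile factors, 0.859 with at least 5 CPM, 0.913 with DESeq2, 0.931 with limma-voom, 0.962 with the replicate block, 0.863 with fry and 0.636 to 0.967 with 1 library left out. For TGF-beta ligands, receptors and SMADs it was 0.859 with at least 5 CPM, 0.756 with DESeq2, 0.946 with fry and 0.579 to 0.938 with 1 library left out. For G1/S it was 0.853 with the length correction, 0.946 with fry and 0.161 to 0.805 with 1 library left out. The neutrophil list was at 0.509 with no filter on low counts, and the monocyte list at 0.934 with at least 5 CPM and 0.616 to 0.935 with 1 library left out. Reported miR-125b targets were at 0.878 with the length correction and 0.803 with it and without LUC library 2, mitochondrially encoded genes at 0.853 and 0.819. The p53 list was at 0.924 with the length correction without LUC library 2 and at 0.213 to 0.949 with 1 library left out. The MYC list ran from 0.00136 without LUC library 2, as higher, to 0.90 without LUC library 3, as lower. Why single libraries moved these calls was not tested.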

Other observations

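The tests and the splits in this part were all chosen after the results were seen. The immediate early genes varied between the Arid3a-FLAG libraries. Fosb had 5.96, 2.84 and 17.4 CPM there against 0.347, 0.262 and 0.540 CPM with LUC, and Fos had 6.83, 1.80 and 8.04 CPM against 1.33, 0.392 and 1.08 CPM.

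When the 6 libraries were split into 3 and 3 in all 10 ways, the real split gave 994 genes past the threshold. The highest other split gave 1, so 1 split, the real one, had a result as large. Each other split mixed libraries of both groups, so any difference between Arid3a-FLAG and LUC raised the spread within its parts. The 994 against 1 therefore cannot show how many genes would pass without a group difference. For gene lists the real split gave 8 calls and the highest other split gave 9, and 4 splits had as many calls or more, the real one included. A share under 0.05 cannot come from 10 splits. List calls as many as those of Arid3a-FLAG against LUC also arose between mixed groups.

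The log2 fold change rose with exon length, from a median of -0.22 in the shortest genes to 0.10 in the longest. The length profile of LUC library 2 is a candidate explanation for part of the trend: without that library rho fell from 0.324 to 0.165, below the 0.305 to 0.363 seen when any other library was left out. The tables argue against the length trend alone accounting for most of the genes past the threshold. After the length correction 88.7% of them, 882 of 994, remained past it in the same direction. In all, the correction called 608 genes higher and 644 lower, more than the 467 and 527 of the main comparison. It can also remove spread between libraries of a group, so a gene can keep its call with a smaller fold change. The kept calls therefore do not show how much of each change came from the trend. The direction of the calls did follow length. Among the shortest genes 20 were higher and 144 lower, and among the longest 187 and 62. After the correction these were 58 and 97 among the shortest, and 158 and 158 among the longest. The lower ribosomal protein genes, which are short, moved with this trend. What gave LUC library 2 its profile, and what part of the remaining trend is biological, stays open.

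Some genes of the mast cell, neutrophil and lymphoid lists fell with Arid3a-FLAG, 3 of 22, 3 of 6 and 3 of 4 tested, among them Ms4a2, Mcpt8, Ms4a3 and Nkg7, while Slc6a4 rose; the mast cell set passed, though not with an estimated correlation (adjusted p = 0.839), the neutrophil set did not, and the lymphoid list was too short to test. The exon length trend could lower short genes. All 9 of the genes that fell were still lower past the threshold after the length correction, and 8 with it and without LUC library 2, where Prtn3 was lost. The smallest of these falls, that of Prtn3 (-1.01), was larger than the median of -0.22 in the shortest genes, and Lef1 (8788 bp of exon) is not short. These genes were picked as called lower, so most were likely to stay called. Their kept calls do not test the trend for the lists as a whole. Loss of a mast cell population that is the only source of the mast cell transcripts would lower all of them alike. The 17 mast cell genes of at least 20 CPM had a median log2 fold change of -0.27 and a robust SD of 0.54. The smallest called fall was -1.24, but it came from members already called lower, so the median was likely to lie above it. Slc6a4 rose, so the list did not fall alike, but platelets also use that gene. The comparison therefore cannot decide whether mast cells were lost. Loss of such a population stays open. A smaller shift in cell types and a change within each cell also stay open and untested.

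Higher immediate early genes, such as Fosb, Fos and Dusp4, may come from a stress at harvest that differed between the groups. Atf3 and Nr4a1, which such a stress often raises, had log2 fold changes of -0.53 (SE 0.47) and 0.05 (SE 0.30), and neither passed. These intervals are wide and harvest cannot be told apart from the group here, so the test cannot tell. An effect of Arid3a on these genes stays open and untested.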
